A study of Mus musculus with 71 samples.

How the data were processed

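Striatal RNA of embryos, juveniles and adults was hybridised to 1-colour oligonucleotide arrays after biotin labelling of cRNA, per the labels' protocols. Embryonic and adult striata were dissected whole under a microscope, together with the pallidum, and juvenile striata were punched from coronal slices, per the labels' protocols. The values deposited by the authors are log2 expression values, 1 row for each of 15768 mouse genes with an Ensembl identifier, so probes had been regrouped by gene before deposit. The array background correction, normalization and summary method are not given in the sources used here. Values ran from 3.26 to 14.5 and none was at or below 0. The 35 juvenile columns carry fewer decimals than the 36 embryonic and adult columns, so these parts may have been computed separately; comparisons were made within 1 of them, except the averaged humanised effect and its difference between settings, whose fit joins both. No table column was left unused. None of the row identifiers could be matched to a symbol: the table of mouse genes at hand (assembly GRCm38.p6) pairs 0 of them with a name. For this reason the 31 lists of gene symbols fixed before the data were examined (cell types, synaptic and other pathways, Foxp2 targets and neighbours, sex-linked genes) could not be tested, and Foxp2, Foxp1 and Foxp4 could not be looked up.

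Groups, sex, age, array run and litter came from the labels. Arrays hold separate animals, except 1 pooled array. Genotypes are spread over runs: runs 1 to 3 hold juveniles of both lines, runs 4 and 5 embryos of both genotypes and run 6 the adults. The 71 arrays came from 26 litters, 13 of which hold both genotypes; the pooled array, from 2 of the 26, was given a litter label of its own in litter blocks.

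Genes in the dimmest 40% by mean over all arrays were left out, which kept 9461. Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Embryos were fitted with sex and run, adults with genotype only, and juveniles in 1 fit over both lines with sex, age and run. The averaged humanised effect and its difference between settings came from 1 fit over all 71 arrays with 1 shared spread per gene. Adults and embryos were compared with sex in the fit. Confidence intervals are 95% intervals from limma's moderated standard errors. The number of arrays limits the precision; a typical interval of a log2 fold change was ± 0.15 in line Ki and in line Ko juveniles, ± 0.13 in embryos and ± 0.33 in adults.

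Litter marks shared parentage and so pairs animals. Within-litter correlation of residuals estimated by limma was 0.23 in juveniles, 0.0049 in embryos, -0.057 in adults, 0.11 over all 71 arrays and 0.35 in the comparison of adults with embryos, whose litters are nested in stage. The replicate number in the labels counts littermates and pairs nothing. Fits with litter as a random block and as a fixed block were alternatives.

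The rule for named genes, set together with the comparisons, took for each comparison the 12 largest rises and the 12 largest falls among genes that passed, and the 8 smallest p where fewer than 6 passed. Because identifiers have no names here, at most 2 rising and 2 falling genes are given for a comparison, which departs from that rule. Genes of the sex check that the filter removed, and the values of ENSMUSG00000029563_at and ENSMUSG00000041390_at in further comparisons, were added after their values were seen.

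Each fit was tested on simulated data: means, residual SDs and designs came from the real arrays, and 200 genes were changed by 0.25, 0.5 or 1 on the log2 scale. In the line Ko comparison, 40.3% of genes changed by 0.25 and 95.5% of those changed by 0.5 were recovered, and 8 of 9261 unchanged genes were called. Errors were drawn independently for each gene and array, without litter effects or correlation between genes, so the recovered shares hold for such data only. Changing 200 genes together also eases the adjusted threshold, so a single changed gene would be recovered less often. Random groupings of the real arrays called up to 34 genes for the knock-out effect and 3569 for the humanised effect in adults. Correlations of fold changes and gene group shifts were tested by permuting genotype within runs (100 and 100000 permutations) or, in adults, over all 462 splits. Alternatives fixed before the data were examined were no filter, a 60% filter, quantile normalization, median centring, no trend, array quality weights, an adjusted p of 0.10, litter blocks, fits without sex or run, single runs, single lines or sexes, the pooled array left out and each adult array left out in turn. Those added after seeing the data were the permutation test of ENSMUSG00000029563_at, the first adult principal component as a covariate, separate spreads per setting, gene groups taken from the table (at most 500 genes each, by p), the test of whether the age change differs between lines, litter blocks for further comparisons, embryos of 1 run, and the removal of 2 juvenile arrays that stand apart or of 1 female array.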

Results

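Gene expression was measured in the striatum, the large input nucleus of the basal ganglia, of mice with altered Foxp2, a transcription factor gene. Each of 71 oligonucleotide arrays carried labelled RNA of 1 animal, except 1 array of line Ko whose RNA was pooled from animals of 2 litters. Humanised mice (hum) were homozygous for an allele carrying the human-type substitutions of the gene, and knock-out mice (ko) had 1 allele that makes no functional product. Wild-type animals (wt) came from the same crosses. Line Ki and line Ki2 carry the humanised allele and come from separate embryonic stem cell clones, so that results could be checked in an independent line. Line Ki was measured only in juveniles and line Ki2 only in embryos and adults, so no age was measured in both. Line Ko carries the knock-out allele and comes from the same clone as line Ki.

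The juvenile set held 35 arrays of animals aged 15, 18 or 21 days, with 11 hum and 6 wt animals of line Ki and 12 ko and 6 wt animals of line Ko. Line Ki2 gave 25 embryonic arrays at E16.5 (13 hum, 12 wt) and 11 arrays of adult females at 95 days (6 hum, 5 wt). The array medians lay between 6.82 and 6.98 on the log2 scale. No array duplicated another, and the correlation between arrays of a group ran from 0.964 to 0.997. The number of arrays limits the precision. The table names genes by Ensembl identifiers and pairs none of them with a gene name, so genes appear here by identifier, Foxp2 could not be looked up by name, and no pathway or cell type list could be tested.

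Loss of 1 Foxp2 allele was compared with wild type within line Ko. ENSMUSG00000029563_at was the gene that fell, with a mean log2 value of 9.12 ± 0.23 (SD, n = 12) in ko and 9.71 ± 0.22 (SD, n = 6) in wt juveniles. The log2 fold change was -0.59 with a standard error of 0.08 (limma, adjusted p = 0.000829), which leaves 66.6% of the wild-type level. All 12 ko arrays lay below all 6 wt arrays of the line, the highest ko array at 9.40 and the lowest wt array at 9.42. None of the 23 other juvenile arrays, wt or hum, lay below the highest ko array. No other gene passed.

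At an unadjusted p under 0.05 there were 175 genes in this comparison, where 473 would be expected by chance. Random groupings of these arrays gave from 65 to 1620, and 83 of 100, the real one included, gave as many as 175. For 98.9% of genes the 95% confidence interval excluded a change of 1.5-fold or more. Within runs 1, 2 and 3 the log2 fold change of ENSMUSG00000029563_at was -0.49, -0.58 and -0.70, and it passed in none of them (adjusted p = 0.998, 0.785 and 1). With litter as a random block it was -0.58 (adjusted p = 0.000102). In a fit of the line Ko arrays alone it was -0.60 with an adjusted p of 0.0709, which ended the call, and a permutation test of this gene within runs of that line gave p = 0.00567 (two-sided, 100000 permutations). That p does not allow for the gene having been picked from 9461 on the same arrays.

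**Figure D1:**
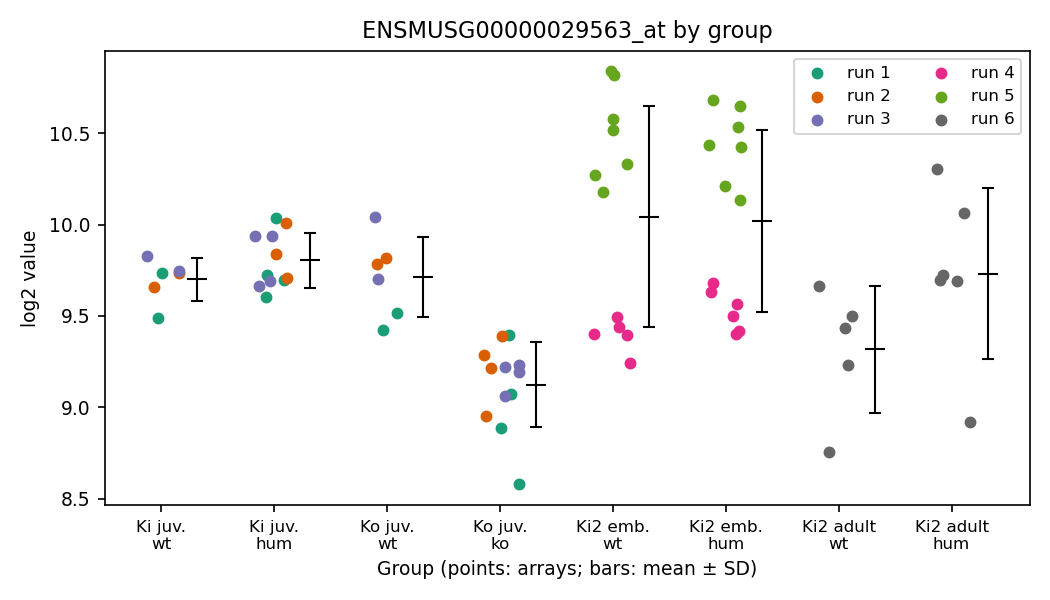
Log2 value of ENSMUSG00000029563_at on each array (points, coloured by array run) in the 8 groups, with the mean and SD of each group beside the points. The 12 ko arrays lie below the 6 wt arrays of line Ko, and embryonic arrays of run 5 lie above those of run 4 in both genotypes.

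The humanised allele was compared with wild type in juveniles of line Ki. No gene passed (0 of 9461 by limma; smallest adjusted p = 0.837), and 292 genes had an unadjusted p under 0.05. ENSMUSG00000029563_at was at 9.80 ± 0.15 (SD, n = 11) in hum and 9.70 ± 0.12 (SD, n = 6) in wt animals, a log2 fold change of 0.11 with a 95% confidence interval from -0.06 to 0.29. The gene with the smallest p, ENSMUSG00000029571_at, was at 6.59 ± 0.13 (SD, n = 11) in hum and 6.87 ± 0.09 (SD, n = 6) in wt animals (adjusted p = 0.837). For 98.4% of genes the interval excluded a change of 1.5-fold or more. In data simulated for this comparison, 89.6% of genes changed by 0.5 on the log2 scale were recovered, and 49.3% of those changed by 0.25. These shares hold for 200 genes changed at once and not for a single one. Runs 1 and 2 on their own gave 0 genes and run 3 gave 1.

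Whether the humanised and the knock-out effect differ was tested directly. ENSMUSG00000029563_at passed, with a difference in log2 fold change of 0.70 and a standard error of 0.12 (limma, adjusted p = 0.0215), and it was the 1 gene that did. Without run in the fit the difference was 0.69 with an adjusted p of 0.103, which ended the call. Within runs 1, 2 and 3 it was 0.69, 0.79 and 0.77, and no gene passed in a single run. At an unadjusted p under 0.05 there were 395 genes.

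As a control for differences that do not involve Foxp2, wt juveniles of the lines Ki and Ko were compared. ENSMUSG00000035757_at was higher in line Ki, at 6.66 ± 0.16 (SD, n = 6) against 6.22 ± 0.17 (SD, n = 6), a log2 difference of 0.44 with a standard error of 0.07 (limma, adjusted p = 0.00864). The same gene stood at 6.42 ± 0.19 (SD, n = 11) in hum juveniles of line Ki, a value that did not differ from wt after adjustment, and both comparisons use the same Ki wt arrays. An unadjusted p under 0.05 was found for 880 genes; random groupings of these arrays gave from 65 to 1122. The call was lost with litter as a random block (adjusted p = 0.0616) and in each run on its own (0 genes).

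In embryos of line Ki2 the humanised allele changed no gene past the threshold (0 of 9461 by limma; smallest adjusted p = 0.37). ENSMUSG00000041390_at had the smallest p, at 7.80 ± 0.50 (SD, n = 13) in hum and 6.97 ± 0.38 (SD, n = 12) in wt embryos, a log2 fold change of 0.81 with a standard error of 0.17. Its log2 fold change was 0.66 in adults, with a 95% confidence interval from -0.22 to 1.54, and -0.01 in juveniles, with an interval from -0.21 to 0.20. ENSMUSG00000029563_at was at 10.0 ± 0.50 (SD, n = 13) in hum and 10.0 ± 0.61 (SD, n = 12) in wt embryos. At an unadjusted p under 0.05 there were 465 genes, close to the 473 expected. The interval excluded a change of 1.5-fold or more for 99.5% of genes. In data simulated for this comparison, 97.0% of genes changed by 0.5 on the log2 scale were recovered. There 200 genes were changed at once, so the share does not hold for a single changed gene. Run 4 and run 5 on their own gave 0 genes each. The log2 fold change of ENSMUSG00000041390_at was 0.28 in run 4 and 1.04 in run 5. All hum embryos of run 4 were female, while its wt embryos were of both sexes. With sex in the fit, the run 4 value thus rests on only a part of its wt embryos.

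In adults of line Ki2 no gene passed either (0 of 9461 by limma; smallest adjusted p = 0.709). The gene with the smallest p, ENSMUSG00000021493_at, was at 6.23 ± 0.07 (SD, n = 6) in hum and 6.75 ± 0.22 (SD, n = 5) in wt animals, and 643 genes had an unadjusted p under 0.05, or 1445 with the first principal component as a covariate, chosen after seeing the data, where 0 passed. The adult arrays stood in 2 sets on the first principal component, which held 49.3% of their variance: 5 arrays, 3 hum and 2 wt, scored from -25.1 to -21.4, and 6 arrays, 3 hum and 3 wt, scored from 12.8 to 27.4. The median 95% confidence interval of a log2 fold change was ± 0.33, against ± 0.13 in embryos, and the interval excluded a 1.5-fold change for 68.4% of genes. In data simulated for the adults with 200 genes changed at once, 16.4% of genes changed by 0.5 on the log2 scale were recovered. Of those changed by 1, 77.3% were recovered. All arrays came from 1 run and 1 sex, so neither entered the fit. ENSMUSG00000029563_at had a log2 fold change of 0.42 in adults, with a 95% confidence interval from -0.08 to 0.91 (limma, adjusted p = 0.715).

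**Figure D2:**
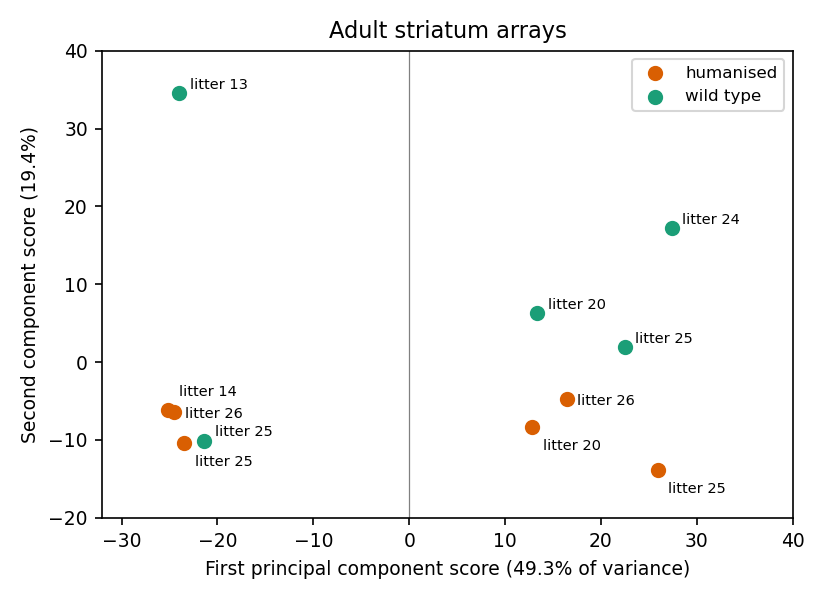
Scores of the 11 adult arrays on the first principal component (horizontal, 49.3% of variance) and the second (vertical, 19.4%), coloured by genotype and marked with the litter. Arrays of both genotypes lie on both sides of 0, and so do arrays of litters 25 and 26.

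The humanised effect was averaged over line Ki juveniles, line Ki2 embryos and line Ki2 adults. Such an average does not measure reproducibility, because a large effect in 1 setting can carry it. Line, stage and dissection also change together between line Ki and line Ki2. In 1 fit over all 71 arrays, 43 genes passed (limma), 19 higher and 24 lower in hum animals. ENSMUSG00000032307_at was higher, with an averaged log2 fold change of 0.33 and a standard error of 0.07 (adjusted p = 0.0209), and ENSMUSG00000007944_at was lower, at -0.39 with a standard error of 0.08 (adjusted p = 0.0209). In the adults alone their log2 fold changes were 0.73 and -0.78, in embryos 0.19 and -0.06, and in line Ki juveniles 0.07 and -0.33. The call was lost for all 43 genes when each setting kept its own spread, a choice made after seeing the data: then 0 genes passed (882 at an unadjusted p under 0.05). After quantile normalization 52 genes passed, 32 higher and 20 lower, against 19 and 24 without it.

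Log2 fold changes of the 4 genotype comparisons, each fitted on its own arrays, were then correlated across the 9461 genes, which are not independent replicates. The correlation was 0.17 between embryos and adults of line Ki2, 0.08 between embryos and line Ki juveniles, and 0.09 between adults and line Ki juveniles. Between the humanised and the knock-out effect in juveniles it was -0.07. By these Pearson correlations none of the 6 pairs stood out against 100 permutations of the genotype within runs (smallest p = 0.1, adjusted p = 0.6). For embryos and adults the middle 95% of permuted correlations ran from -0.20 to 0.19. The Spearman correlation of that pair was 0.25, above the permuted range of -0.19 to 0.21 (p = 0.04), and did not pass after adjustment over the 6 pairs (adjusted p = 0.24).

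A direct test of whether the humanised effect differs between the 3 settings passed 4 genes (limma), among them ENSMUSG00000002625_at (adjusted p = 0.0119). The count depended on the analysis, from 1 after quantile normalization to 22 with the dimmest 60% of genes left out and 1401 with array quality weights, and 962 genes had an unadjusted p under 0.05.

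Between 15 and 21 days of age 2796 of 9461 genes changed in the juvenile striatum (limma), 1077 rising and 1719 falling. ENSMUSG00000026255_at rose most, by 1.66 on the log2 scale with a standard error of 0.13 (adjusted p = 1.11e-10), and ENSMUSG00000038932_at fell by 1.61 with a standard error of 0.14 (adjusted p = 1.1e-09). Changes were small as a rule: the median was a rise of 0.23 among rising genes and -0.23 among falling ones, and 17 genes changed more than 2-fold. Of the 2796 genes, 2604 (93.1%) had their 18-day level between those of 15 and 21 days, and the median gene had covered 60.1% of its change by 18 days. The genes were picked on these arrays for a gap between 15 and 21 days, which by itself tends to place the 18-day level between. The share to be expected from that choice was not computed. The step from 15 to 18 days alone passed 740 genes and that from 18 to 21 days 81. These counts and the 60.1% pool both lines and need not hold for each.

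The age change recurred between lines. With each line fitted alone, 1866 genes passed in line Ki and 1490 in line Ko; 547 passed in both, where independent lists would share 294, and 540 of these went the same way. The log2 changes of the lines correlated across genes with r = 0.43. Genes that rose or fell with age in 1 line separated 15 from 21 days in the other, while 18-day arrays overlapped both: the mean of rising minus falling genes was -0.06 ± 0.15 (SD, n = 6) at 15 days and 0.45 ± 0.13 (SD, n = 5) at 21 days in line Ki, and -0.19 ± 0.13 (SD, n = 6) and 0.22 ± 0.11 (SD, n = 7) in line Ko. At 18 days this mean was 0.35 ± 0.19 (SD, n = 6) in line Ki, nearer its 21-day mean. In line Ko it was -0.03 ± 0.12 (SD, n = 5), nearer its 15-day mean. In line Ki each litter held 1 age and each age came from 2 litters, so its age change was compared wholly between litters. The counts for each line alone did not allow for litter. Over both lines, with litter as a random block, chosen after seeing the data, 2023 genes passed. Run 1, 2 and 3 on their own gave 183, 29 and 107 genes.

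**Figure D3:**
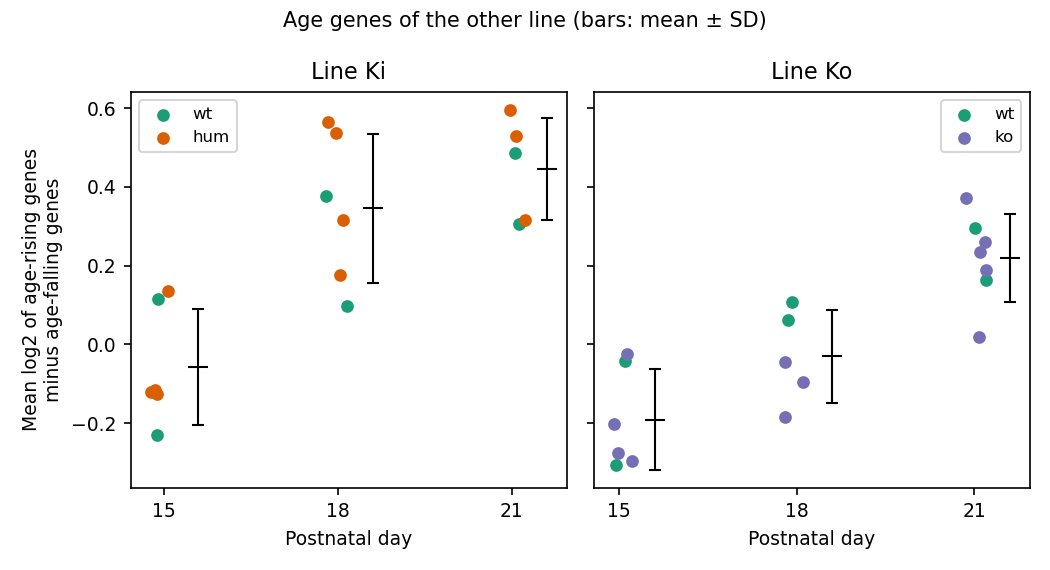
Mean log2 value of age-rising genes minus that of age-falling genes (vertical) against postnatal day (horizontal) for each juvenile array of line Ki and line Ko, with the genes taken from the other line and the mean and SD beside the points. In line Ki the mean goes from -0.06 at 15 days over 0.35 at 18 days to 0.45 at 21 days. In line Ko it goes from -0.19 over -0.03 to 0.22.

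Whether genotype moves such developmental genes was tested with groups taken from other arrays, chosen after seeing the data because named lists could not be matched. Of 461 genes that rose with age in line Ko, 373 had a positive log2 fold change in hum juveniles of line Ki, and of 500 that fell with age, 373 had a negative one. In ko juveniles the signs were the other way round, with 374 of 500 age-rising genes negative and 315 of 500 age-falling genes positive. These shifts were small, 0.06 with a standard error of 0.04 for age-rising genes in hum and -0.04 with a standard error of 0.02 in ko juveniles. Camera with a preset correlation called age-rising genes in both (adjusted p = 1.26e-07 and 2.51e-05) and age-falling genes in both (adjusted p = 5.68e-07 and 0.000186). With an estimated correlation neither group was called, at an adjusted p of 0.304 for each in hum and 0.12 for each in ko juveniles. A permutation of the genotype within runs called none of the 12 group and setting pairs (smallest adjusted p = 0.605). Neither camera nor this permutation allowed for litter, and the hum juveniles of litters 3 and 4 had no wt littermate on an array. At 18 days hum arrays scored 0.57 and 0.54 in litter 4 (rising minus falling genes). In litter 1, hum arrays scored 0.18 and 0.32 and wt arrays 0.098 and 0.38. At 21 days the hum array of litter 3 scored 0.53. In litter 2, hum arrays scored 0.60 and 0.32 and wt arrays 0.49 and 0.31. Genotype and litter are thus only partly separated here. The groups of genes higher in adults or in embryos were called by camera in hum and in ko juveniles with the preset correlation (adjusted p from 2.71e-05 to 0.0258) and not with the estimated one (adjusted p from 0.304 to 0.333). In embryos and adults of line Ki2, camera called neither age group (smallest adjusted p = 0.153).

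Adults and embryos of line Ki2 differed in 6607 of 9461 genes (limma), 3140 higher in adults and 3467 higher in embryos, 2621 of them by more than 2-fold. ENSMUSG00000046480_at was higher in adults by 7.53 on the log2 scale with a standard error of 0.17, at 12.7 ± 0.34 (SD, n = 5) in wt adults and 5.18 ± 0.31 (SD, n = 12) in wt embryos. ENSMUSG00000024501_at fell by 5.78 with a standard error of 0.19, from 12.8 ± 0.13 (SD, n = 12) to 7.04 ± 0.45 (SD, n = 5). Of 2070 genes that passed both here and between 15 and 21 days, 1467 (70.9%) changed in the same direction; over all genes tested 56.1% had the same sign, with a correlation of 0.32. Run cannot be told apart from stage in this comparison, because embryos were in runs 4 and 5 and adults in run 6. The embryonic runs 5 and 4 alone differed in 6328 of 9461 genes, 342 of them by more than 2-fold. The 6607 genes can therefore not be read as a count of developmental genes.

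Males and females differed in few genes, and the test served as a check of the sex labels. ENSMUSG00000072485_at was higher in females, at 10.4 ± 0.26 (SD, n = 13) against 4.76 ± 0.27 (SD, n = 12) in male embryos and at 10.1 ± 1.41 (SD, n = 18) against 4.63 ± 0.16 (SD, n = 17) in juveniles. By limma 4 genes passed in juveniles and 4 in embryos, all lower in males, and 3 passed in both. Without the filter, 9 and 13 genes passed, and 4 male-high genes, which were too dim on average to enter the filtered test, passed in both stages and separated all males from all females; among them ENSMUSG00000069045_at was higher in males by 4.69 in juveniles and 3.84 in embryos on the log2 scale. On 1 array labelled female, wt replicate 1 of line Ki, ENSMUSG00000072485_at was at 4.49, inside the juvenile male range of 4.28 to 4.89, while ENSMUSG00000069045_at was at 3.89, inside the range of the other juvenile females, 3.74 to 4.03.

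**Figure D4:**
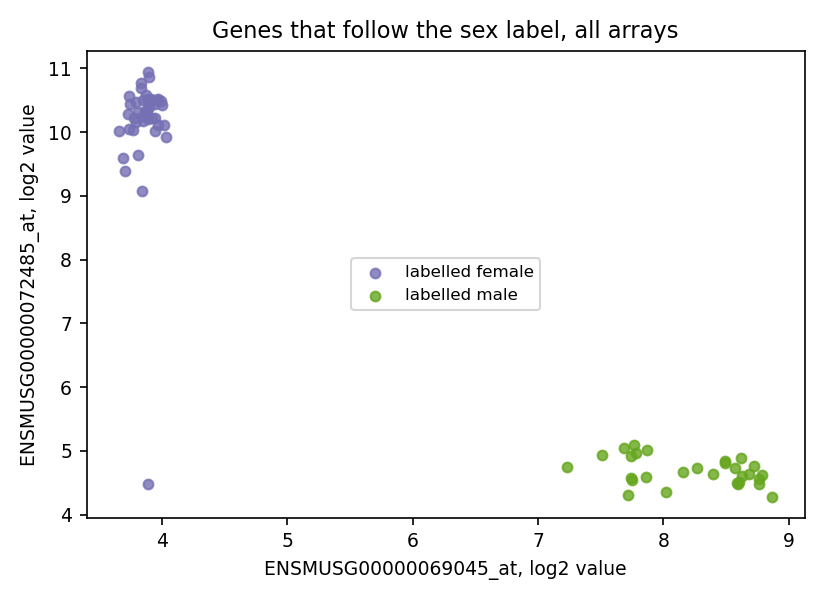
Log2 values of ENSMUSG00000069045_at (horizontal) and ENSMUSG00000072485_at (vertical) on all 71 arrays, coloured by the sex in the labels. Males lie at the lower right and 41 of 42 females at the upper left; 1 female is low for both genes.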

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

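The tests of explanations for the ko gene and the adult sets and the test of age change by line were chosen after the results were seen, and the bounds for reading all random groupings were written after their counts were known.

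ENSMUSG00000029563_at was the 1 gene whose humanised and knock-out effects differed. The gap between ko and wt was -0.49 in run 1, the run where it was nearest to 0. Runs 1, 2 and 3 each held 4 ko and 2 wt arrays of line Ko, and run was in the fit. The design thus already kept run differences from making the gap, and the values by run add no support. With litter as a fixed block the gap was -0.55, which argues against litter. A candidate explanation is that this identifier is the gene made non-functional in line Ko. Its log2 fold change of 0.11 in hum juveniles, whose copies are intact, does not decide this, because the gene was picked for its fall in ko, and the identifier was not matched to a name. This stays an untested hypothesis. Random groupings of the arrays gave 1 or more genes in 6 of 100 splits for the knock-out effect (real count 1, highest other 34). For the difference they did so in 5 of 100 (real count 1, highest other 27), so for the bare counts chance is not excluded. Why some splits call that many more genes was not tested.

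The humanised effect differed between settings for 4 genes, and 49 of 100 random groupings gave as many, the highest other 3037. The averaged effect passed 43 genes, and 10 of 100 groupings gave as many, the highest other 2374, so chance is excluded for neither. What makes some splits call so many more genes than the real one was not tested. In adults alone 0 genes passed, so all 100 groupings gave as many by construction, and the highest other gave 3569; at an unadjusted p under 0.05, 21 of 100 groupings gave as many as the real 643.

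The adult arrays lie in 2 sets on their first principal component; whether this gives rise to the large counts of the random groupings was not tested. The lower quartile of the arrays also differed between the sets, 5.14 to 5.18 against 5.22 to 5.36. After quantile normalization, which makes the quartiles equal, the component still held 49.3% of variance with all 11 arrays on the same side, which argues against array-wide normalization as the whole source. The smaller set held 3 of the 6 hum arrays (exact permutation test of the scores by genotype, two-sided p = 0.654), which argues against genotype, and arrays of 2 of the 3 litters with several arrays lay on both sides, which argues against litter. The tissue taken, or the handling of single brains, may be the source: loadings correlated across genes with the first residual axis of juvenile arrays at 0.447 in absolute value, but with another juvenile axis at 0.515, and marker genes could not be looked up, so this cannot be told apart from other unlabelled causes. No biological explanation other than genotype and litter was tested.

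The change from 15 to 21 days differed between lines Ki and Ko for 119 genes, 87 of them more positive in line Ki. Only 1 gene passed without 2 arrays of line Ko that stand apart, the females of litter 8 in run 1 at 15 days (ko replicate 1 and wt replicate 1), whose first principal component scores were -28.6 and -34.9 where the next lowest was -11.3; with litter as a random block the count was also 1.

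Among 76 outlier tests in groups of 5 or 6 arrays, 2 arrays stood out, where chance would give 3.8. ENSMUSG00000041607_at, which was among the genes higher in adults than in embryos, was at 13.4 in wt replicate 1 of line Ki, against 13.7 to 13.8 in the other 5 arrays. ENSMUSG00000035757_at was at 6.31 in adult hum replicate 3, against 7.01 to 7.40 in the others.

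For the remaining comparisons, random groupings gave as many genes in 100 of 100 splits, by construction, for the humanised effect in embryos (real 0, highest other 2) and in juveniles (real 0, highest other 0); at an unadjusted p under 0.05, 44 and 48 of 100 gave as many as the real 465 and 292. They gave as many in 2 of 100 for the wild types of lines Ki and Ko (real 1, highest other 1), and in 1 of 100, the real one, for age (real 2796, highest other 81), for adults against embryos (real 6607, highest other 4892), and for sex in juveniles (real 4, highest other 2) and in embryos (real 4, highest other 3). For age and stage, chance in how single arrays were grouped is excluded. For sex it is excluded for the counts of genes that passed. At an unadjusted p under 0.05, 10 of 100 groupings in juveniles and 7 of 100 in embryos gave as many as the real 1067 and 789. Between the lines chance is not excluded, since another grouping gave as many genes and 5 of 100 gave as many at an unadjusted p under 0.05. The real grouping is included in all these shares. The groupings did not keep litters together; with litter as a random block the call between the lines was lost (adjusted p = 0.0616), while 6554 genes passed between adults and embryos.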

How the results depend on the processing

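Of 192 counts, correlations and shifts recomputed under an alternative, 145 kept their side of the threshold or stayed within 1.5 times the main value, 22 were stronger, 23 weaker and 2, shifts that were not called, moved; of 581 log2 fold changes of named genes 546 kept their call and none reversed. The litter pairing as a replicate block gave 0, 0, 0 and 1 genes for the humanised effect in embryos, adults and juveniles and for the knock-out effect, as without it, random or fixed. Leaving out each adult array in turn gave 0 to 0 genes. The causes of the changes below were not tested, except that single runs, lines or sexes hold fewer arrays and other filters test other numbers of genes.

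Without the filter the counts were 1 for the humanised effect in juveniles, 1 for its difference between settings, and 9 and 13 for sex in juveniles and embryos. With the dimmest 60% left out, the line comparison gave 0, the averaged effect 115 and the difference between settings 22. For that difference, quantile normalization gave 1 and median centring 7. Array quality weights gave 1 gene in embryos (humanised), 10 between lines, 2241 for the averaged effect, 1401 for the difference between settings, and 9 and 7 for sex in juveniles and embryos. At an adjusted p of 0.10 there were 2 between lines, 416 averaged, 63 between settings and 18 for sex in embryos. The line comparison gave 0 without sex or without run, and the difference of humanised and knock-out effects 0 without run. In males only, 1 embryonic gene passed.

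Run 1 alone gave 0 for the knock-out effect, its difference from the humanised one and the lines, and 183 for age. Run 2 alone gave 0, 0, 0 and 29. Run 3 alone gave 0 for the difference and the lines, 107 for age, and 1 for the humanised effect; its 1 knock-out gene was another gene, higher in ko. Line Ko alone gave 0.

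Chosen after seeing the data: the adult principal component as a covariate gave 319 for the averaged effect and 47 between settings; separate spreads gave 0, also with adults left out (0). Litter as a random block gave 0 between lines, 24 between settings and 1 for age by line. Without the 2 juvenile arrays that stand apart there were 2 between lines and 1 for age by line. Quantile normalization changed the sign of the shift of age-rising genes, to 0.00096 in embryos and 0.021 in adults, neither called. Not run: every probe set on its own and the mean of probe sets, since the table has 1 row per gene, and all tests of named gene lists, for lack of names. Signal over background is not in the table, so what dim genes lose cannot be given.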

Other observations

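All tests in this part were chosen, or their bounds written, after the values were seen. The embryonic runs differed widely from each other. Between run 5 and run 4, 6328 of 9461 genes differed (limma), 3911 higher in run 5 and 342 of all by more than 2-fold. After quantile normalization 6486 did, 3272 of them higher in run 5, so the excess of genes higher in run 5 depended on the scaling. ENSMUSG00000029563_at was among the 6328 genes, higher in run 5 by 1.06 on the log2 scale. It stood at 9.40 ± 0.09 (SD, n = 5) in wt embryos of run 4 and 10.5 ± 0.26 (SD, n = 7) in those of run 5. The labels mention a second batch of embryos without tying it to a run, and no litter was in both runs, so batch, litter and exact developmental age cannot be separated. Juvenile runs differed far less: run 2 from run 1 in 602 genes and run 3 from run 1 in 83.

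The array of wt replicate 1 of line Ki, labelled female, lacks the signal of ENSMUSG00000072485_at that the other 41 female arrays show. Of the 4 male-high genes, 0 were in the male range on it, which argues against a male labelled female. Its median correlation with the other juvenile arrays was 0.991, and 4 juvenile arrays had a lower one, fewer than the 5 that would have argued against a faulty array, which stays open. All 3 female-high genes were in the male range, 1 of them also in the female range, and the other 2, ENSMUSG00000072485_at and ENSMUSG00000037369_at (8.14, against 8.34 or more in other juvenile females), lay below every other juvenile female, the first being the gene that picked out this array. A candidate explanation, offered as a hypothesis, is an animal with 1 X chromosome; the identifiers were not placed on chromosomes here, which a test of it would need.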
